A study of Danio rerio with 6 samples.

How the data were processed

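Total RNA from livers of zebrafish larvae aged 7 days post fertilization was made into stranded Illumina libraries and read as single-end 50-bp reads, per the labels. The 6 libraries fall into wild-type and foxn3-transgenic groups of 3 by the titles, which also number them 1 to 3. Reads were aligned with Novoalign to the Zv9 zebrafish assembly, and the authors' comparison was made with DESeq2, per the submitters' processing notes. Their versions are not given in the sources used here.

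The authors counted the alignments that overlap each gene by at least 1 bp and deposited these counts unnormalized for each library, per the file headers. IDs with fewer than 10 counts (with those over 50000 counts) were set on a separate list by the authors, 10508 as low and 6 as high, and 0 of them are in the count table. The largest count in the table is 541333, for tfa, so the upper limit the authors name was not applied to single counts, and how it was applied is not given in the sources used here. Whether the counting used strand is not stated, so reads from overlapping antisense genes cannot be told apart. The authors' FPKM values are counts scaled to exon length and to the library total, per the file headers. Recomputed from the counts and the deposited gene lengths in base pairs, FPKM differed by at most 4e-13%. The deposited regularized log2 values are DESeq2's, per the file headers, and were not used in a test. The deposited log2 ratios (transgenic over wild type) and the deposited scores, which are 10 times the negative log10 of DESeq2's adjusted p-value, are the authors' own comparison, and the scores were turned back into p-values here. The authors' exon values are a log2 ratio and a score from a chi-square test with Bonferroni correction, per the file headers. Coordinates are as the deposited table gives them in Zv9, and whether they count from 0 or 1 is not stated. Gene symbols are those of the table. A reference table of names was used for list members under newer symbols and gave a symbol for 17069 of the IDs.

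Differential expression was tested in R 4.3.3 with edgeR 4.0.16 on the counts as deposited: TMM normalization, filterByExpr by group, glmQLFit and glmQLFTest, with transgenic minus wild type as the direction, no covariate and Benjamini-Hochberg adjustment over the 19573 genes tested at a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. Levels are CPM, the count of a gene relative to the TMM-scaled library total, as mean ± SD of 3 libraries. TMM factors were 1.03, 1.07 and 0.967 for wild-type and 1.04, 0.848 and 1.06 for transgenic libraries. Total counts of 7732478 to 12550954 set the precision of low genes, and counting error is only part of the spread between libraries. Pairs of libraries within a group differed by 17.5 to 30.7 chi-square units per gene, far above sampling noise, so none was treated as a duplicate.

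Before the data were examined, 37 gene lists were fixed, 25 of pathways and 12 of cell type markers. Of their 929 names, 738 matched a symbol of the table and 72 a reference symbol alone, and these 810 names gave 853 gene entries. The pathway lists were glycolysis, gluconeogenesis, glycogen metabolism, ribosome biogenesis and growth genes, cytosolic ribosomal proteins, fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation, bile acids, lipoproteins, coagulation and plasma proteins, complement and acute phase, amino acid breakdown and urea cycle, one-carbon metabolism, xenobiotic metabolism, oxidative stress, unfolded protein response, heat shock, cell cycle, circadian clock, insulin and FOXO signalling, liver transcription factors, mitochondrially encoded transcripts, nuclear oxidative phosphorylation and vitellogenins. The marker lists were exocrine pancreas, islet, intestine, erythrocyte, skeletal muscle, skin, eye and nervous system, bile duct, endothelium, stellate cells and fibroblasts, leukocytes and kidney. Lists were tested with camera (limma 3.58.1, two-sided) on log2 CPM with a prior count of 2, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry. Adjusted p-values of lists are Benjamini-Hochberg over the 37 lists. A list's score in a library is the mean of its genes' log2 CPM, each relative to its mean over the 6 libraries, and scores of the groups were compared with exact two-sided permutation tests. The 13 lists of liver products and metabolism averaged later were plasma proteins, lipoproteins, complement, liver transcription factors, bile acids, one-carbon metabolism, amino acid breakdown, fatty acid oxidation, xenobiotic metabolism, gluconeogenesis, glycogen metabolism, fatty acid synthesis and vitellogenins, chosen after the results were seen.

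Genes named in the text follow a rule fixed before the data were examined: the genes the study concerns (foxn3, the myc genes, enzymes and transporters of glucose metabolism, igfbp1a and fabp10a), the genes with the largest fold changes among those called, the genes of smallest unadjusted p up to 8 in a direction where few were called, every gene of the authors' short lists, and up to 3 genes of smallest unadjusted p in each list. fabp10a was not analysed here, and not every gene the rule takes is reported here. arntl1b, per2, per3, try and tfa, and the exons, were named after their values were seen.

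Alternatives fixed before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts, the replicate number as a block, each library left out in turn, looser thresholds, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1). Added after seeing the data were edgeR's newer quasi-likelihood method and a fit without wild-type library 2 and transgenic library 2.

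The tests were tried on simulated data for the comparison of transgenic with wild type, drawn from the real means and library sizes with 50 changed genes at each fold. The changed genes were taken only from those with a mean above 2 CPM, so the shares recovered do not cover genes of lower level. edgeR, run on 19083 simulated genes, recovered 4% of genes changed 1.5-fold, 20% at 2-fold, 90% at 4-fold and 98% at 7-fold, with 10 false calls. DESeq2 recovered 4, 36, 92 and 98% with 21 false calls among 19573 genes, and limma-voom 4, 16, 88 and 98% with 10 over 19083. For each tool the share of false calls among its calls was above the threshold of 0.05, and it was largest for DESeq2. Many changed genes in the data make the adjusted threshold easier to pass. In the real data edgeR did not call foxn3 at a 6.69-fold difference (adjusted p 0.11). The simulated shares may therefore overstate the recovery in the real data. In a separate draw camera with the preset correlation found a list of 30 shifted genes, and 5 of 100 unchanged lists came under an unadjusted level of 0.05. All draws had errors independent between genes. The real lists called by camera had estimated correlations from 0.0053 for oxidative stress to 0.85 for exocrine pancreas. The draw therefore does not check camera's calls of correlated lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.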

Results

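RNA was measured in livers of zebrafish (Danio rerio) larvae aged 7 days post fertilization. Larvae carrying a foxn3 transgene were set against their wild-type siblings, with 3 libraries in each group. foxn3 encodes a forkhead-box transcription factor. The deposited table held counts for 21589 genes, and 19573 of these passed the filter on low counts. Total counts ranged from 7732478 in wild-type library 3 to 12550954 in transgenic library 2. They were 10884596 and 12214349 in wild-type libraries 1 and 2, and 11356831 and 10891720 in transgenic libraries 1 and 3. The 10 most abundant genes took 14.6 to 16.2% of the counts of a library. Spearman correlations between libraries across genes lay between 0.938 and 0.976. The first principal component held 35.1% of the variance and did not part the groups: wild-type libraries scored -20.3, -26.3 and 56.3 and transgenic libraries -36.1, 25.6 and 0.79. The labels do not say that the libraries of a group came from separate clutches, pools or animals, so each p-value measures the spread between these samples only, which may be technical.

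The question the series addresses is which liver transcripts differ in level between foxn3-transgenic larvae and their wild-type siblings, with glucose use by the liver as its theme. foxn3 itself (ENSDARG00000012833, chromosome 17, 16406423 to 16526116, plus strand, Zv9) had a normalized count (CPM, relative to the scaled library total) of 198 ± 27.3 in transgenic livers against 29.7 ± 12.3 in wild-type livers (SD, n = 3 each), a 6.69-fold difference. The 3 transgenic libraries held 1983, 2206 and 2540 foxn3 counts and the 3 wild-type libraries 304, 246 and 322. The log2 fold change was 2.74 ± 0.30 (SE), with an unadjusted p of 5.7e-06 and an adjusted p of 0.11 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes, so this test did not call it. DESeq2 gave 2.73 with an adjusted p of 1.1e-14, and over all alternatives the adjusted p ran from 1.1e-14 to 1. Without wild-type library 3 edgeR gave 3.11 with an adjusted p of 0.041. The authors' deposited table lists foxn3 at a log2 ratio of 2.1 with an adjusted p of 7.8e-15. The labels do not say which foxn3 sequence the transgene carries, and reads from the transgene and from the native gene were not told apart here.

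Besides foxn3, the authors' deposited short list held 5 genes, with adjusted p-values of 0.063 to 0.095 in the authors' table. The transcription factor genes mycb and egr1 were on the lower side. mycb, a zebrafish counterpart of the growth regulator MYC, stood at 52.3 ± 23.7 CPM in wild-type and 20.6 ± 3.28 in transgenic livers (SD, n = 3 each), a log2 fold change of -1.35 ± 0.33 (SE). egr1, an immediate early gene, stood at 28.8 ± 9.98 and 11.7 ± 3.09, a log2 fold change of -1.31 ± 0.30. PIPOX, which encodes the peroxisomal enzyme that oxidizes sarcosine and pipecolate, stood at 15.7 ± 6.19 in wild-type and 39.1 ± 8.99 in transgenic livers, a log2 fold change of 1.32 ± 0.30. CR388129.1 had 19.6 ± 4.47 and 42.1 ± 4.06 CPM (log2 fold change 1.1 ± 0.21). The crystallin gene crybb1l3 had 3.95 ± 0.411 and 16.5 ± 14.1, and transgenic library 2 alone held 32.8. Its log2 fold change was 2.06 ± 0.52, and 1.07 without that library. The groups did not overlap for any of these 5 genes. edgeR's unadjusted p was 0.0023 for mycb, 0.0015 for egr1, 0.0013 for PIPOX, 0.00044 for CR388129.1 and 0.0031 for crybb1l3, and its Benjamini-Hochberg adjusted p was 1 for each. DESeq2 as run here gave an adjusted p of 0.11 for crybb1l3 and 0.23 for each of the others. In the authors' table the log2 ratios were -0.99 for mycb, -0.97 for egr1, 0.99 for PIPOX, 0.9 for CR388129.1 and 1.2 for crybb1l3. DESeq2 as run here gave -1.34, -1.3, 1.31, 1.1 and 2.07 in that order. The reason for the smaller values in the authors' table was not tested. Zv9 places mycb on chromosome 2 (31734130 to 31736246, plus strand), egr1 on chromosome 14 (22333788 to 22337652, minus strand) and PIPOX on chromosome 15 (23503644 to 23532411, minus strand).

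Over all 19573 genes edgeR called 0 higher and 0 lower in transgenic livers at a Benjamini-Hochberg adjusted p of 0.05. limma-voom also called 0 in each direction, and DESeq2 called 1 higher, foxn3, and 0 lower. At an unadjusted p under 0.05 edgeR had 170 genes with higher and 271 with lower levels, together 441 or 2.25% of the genes, where chance gives 5%. DESeq2 had 133 and 279. All 3 transgenic libraries lay above all 3 wild-type libraries for 647 genes and below for 616, or 6.45% of the genes, where chance gives 10%. The 441 became 801 without wild-type library 1, 709 without wild-type library 2 and 238 without transgenic library 3.

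Among the genes of smallest unadjusted p with higher levels, npas2, which encodes a partner of the clock protein BMAL, had 14.5 ± 0.735 CPM in transgenic and 7.56 ± 0.814 in wild-type livers (SD, n = 3 each), a log2 fold change of 0.94 ± 0.19. Log2 fold changes were 1.07 ± 0.28 for the lipid droplet gene CIDEC, 0.81 ± 0.22 for the magnesium transporter gene SLC41A2 and 0.81 ± 0.22 for the connexin gene cx44.2. Among those with lower levels, the kinase gene pim1 had 67.0 ± 4.35 against 112 ± 13.2 CPM, a log2 fold change of -0.74 ± 0.18. Log2 fold changes were -0.99 ± 0.26 for cish, -0.78 ± 0.20 for the cytokine receptor family gene crfb2, -0.97 ± 0.27 for the MAP kinase phosphatase gene dusp4 and -2.13 ± 0.61 for the glutamate transporter gene slc1a6, which was at -1.28 without wild-type library 3. cish was at -0.65 without wild-type library 2. fabp6, a bile acid binding protein of the intestine, had a log2 fold change of -6.25 ± 1.6 that rested on wild-type library 2, with 150 CPM there, 2.86 and 3.48 in the other wild-type libraries and 0.338 to 1.22 in the transgenic libraries. It was -2.18 without wild-type library 2. Each of these genes had an adjusted p of 1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

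**Figure D1:**
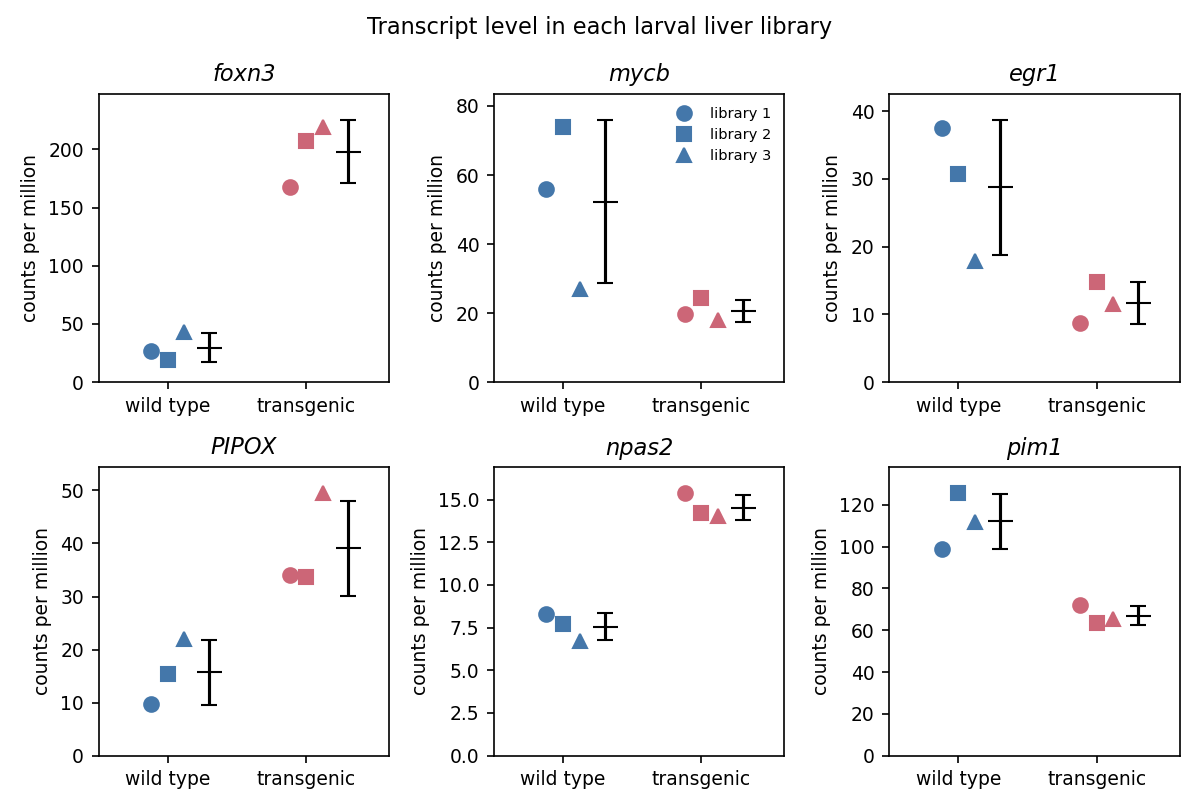
CPM (vertical axis) of 6 genes in each liver library, blue for wild type and red for foxn3-transgenic, with the marker shape giving the library number and the black bars the mean ± SD of each group (n = 3). foxn3 averages 29.7 in wild-type and 198 in transgenic livers and mycb 52.3 and 20.6. The groups do not overlap for all 6 genes, which are among those of smallest unadjusted p, a choice that favors such separation.

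Genes of glucose handling were looked at as a group fixed before the data were examined. gck, which encodes the liver glucokinase, averaged 138 ± 116 CPM in transgenic and 212 ± 54.9 in wild-type livers (SD, n = 3 each), with a log2 fold change of -0.62 ± 0.49. Transgenic libraries 1 and 2, at 80.6 and 62.3 CPM, lay below the wild-type libraries at 273, 167 and 196, while transgenic library 3 stood at 272. Without that library the log2 fold change of gck was -1.57, with an unadjusted p of 0.00045 and an adjusted p of 1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and without transgenic library 2 it was -0.28. The log2 fold changes were 0.15 ± 0.25 for the pyruvate kinase gene PKLR, 0.08 ± 0.38 for pck1 and 0.19 ± 0.22 for pck2 (the cytosolic and mitochondrial phosphoenolpyruvate carboxykinases), 0.10 ± 0.32 for the glucose-6-phosphatase gene g6pca, 0.13 ± 0.24 for the fructose bisphosphatase gene fbp1b and -0.04 ± 0.21 for the glucose transporter gene slc2a2. g6pcb, with at most 2.07 CPM, had a log2 fold change of 0.89 ± 0.42. For igfbp1a, an insulin-repressed gene, the value was -0.20 ± 0.38, and for myca it was -0.53 ± 0.30. Signs of pck1, g6pca, PKLR, fbp1b, slc2a2 and igfbp1a turned when single libraries were left out, for pck1 to -0.32, for g6pca to -0.27, for PKLR to -0.05 and for fbp1b to -0.09 without transgenic library 2. Without that library pck2 was at 0 and g6pcb at 0.55, and without transgenic library 3 myca was at -0.84.

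Of the 22 glycolysis genes tested, 11 had higher and 11 lower levels, with a median log2 fold change of 0 and a mean of -0.05 (camera, adjusted p = 0.92). Gluconeogenesis had 10 of 13 members higher at a median of 0.10 (camera, adjusted p = 0.18), and glycogen metabolism 12 of 18 at 0.06 (0.90). Of the 35 ribosome biogenesis and growth genes, a set of the kind MYC activates, 26 had higher levels, with a median of 0.10 (camera, adjusted p = 0.59). For the 76 cytosolic ribosomal proteins the count was 52 and the median 0.03 (0.43). Transgenic library 2 had the highest score in both lists. For the growth genes it scored 0.56, while transgenic libraries 1 and 3, at -0.32 and -0.20, lay below all wild-type libraries (-0.17 to 0.12). For the ribosomal proteins it scored 0.23, with -0.05 and -0.14 in the other transgenic and -0.18 to 0.13 in wild-type libraries. No member of these 5 lists had an edgeR unadjusted p under 0.05, and 0 passed when adjusted over the list alone.

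All 28 measured genes of the cholesterol synthesis list had positive fold changes, with a median log2 fold change of 0.52, or 1.44-fold (camera with a preset inter-gene correlation of 0.01, adjusted p = 2.6e-15, and adjusted p = 0.76 with an estimated correlation). The median was 0.34 without wild-type library 2, which had the lowest score, and 0.78 without wild-type library 3. Values were 0.98 ± 0.32 (SE) for ebp, which acts late in sterol synthesis, and 0.82 ± 0.30 for acat2, which makes acetoacetyl-CoA. For ebp the mean was 81.1 ± 19.6 CPM in transgenic and 41.1 ± 19.3 in wild-type livers (SD, n = 3 each). 10 members had an edgeR unadjusted p under 0.05, 0 passed over all genes and 0 passed when adjusted over the list alone, where the smallest adjusted p was 0.13. The mean score of the list was 0.27 ± 0.13 in transgenic and -0.27 ± 0.41 in wild-type libraries (SD, n = 3 each), with an exact two-sided permutation p of 0.20. Wild-type library 3, at 0.18, lay above transgenic library 2, at 0.15. 3 libraries against 3 cannot give an exact p below 0.10. Exocrine pancreas markers were also higher in the transgenic group, at 0.46, 1.01 and 0.507% of the counts of the wild-type libraries and 0.685, 1.56 and 1.07% of the transgenic libraries.

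In the oxidative stress response list 17 of 19 genes had positive fold changes, with a median log2 fold change of 0.23 (camera, adjusted p = 0.00013, and adjusted p = 0.38 with an estimated correlation). Values were 0.77 ± 0.28 for the peroxiredoxin gene PRDX1, 0.82 ± 0.34 for the heme oxygenase gene hmox1 and 0.55 ± 0.20 for pgd of the pentose phosphate pathway. PRDX1 was at 0.46 without transgenic library 3 and hmox1 at 0.38 without transgenic library 1. 4 members had an edgeR unadjusted p under 0.05, and 0 passed when adjusted over the list alone or over all genes. Each transgenic library scored above each wild-type library, with means of 0.14 ± 0.07 and -0.14 ± 0.07 (SD, n = 3 each) and an exact two-sided permutation p of 0.10, the smallest possible. Chance alone separates the groups for 10% of lists, so among 37 lists a separation of this kind is no more than chance can supply. Like cholesterol synthesis and the exocrine pancreas markers below, the oxidative stress list was called by camera at the preset correlation without each library in turn.

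Several lists of liver metabolism had small positive medians. In methionine, serine and folate-linked (one-carbon) metabolism 16 of 18 genes had positive values, with a median log2 fold change of 0.17 (camera, adjusted p = 0.0041, and adjusted p = 0.77 with an estimated correlation). PIPOX passed when adjusted over the list alone (edgeR, adjusted p = 0.024), while 0 genes of the list passed over all genes, and PSPH of serine synthesis had 0.60 ± 0.22 and the glycine methyltransferase gene gnmt 0.46 ± 0.18. In amino acid breakdown and the urea cycle 25 of 31 were positive at a median of 0.15 (camera, adjusted p = 0.0042, and adjusted p = 0.88 with an estimated correlation), with 0.77 ± 0.30 for ass1, 0.51 ± 0.21 for fah and 0.55 ± 0.24 for asl. The 24 fatty acid oxidation genes had 20 positive values and a median of 0.16 (camera, adjusted p = 0.026, and adjusted p = 0.95 with an estimated correlation), with 0.70 ± 0.32 for cpt1b, or 0.38 without transgenic library 1. For 43 nuclear genes of oxidative phosphorylation the count was 38 and the median 0.12 (camera, adjusted p = 0.0042, and adjusted p = 0.95 with an estimated correlation). For 13 mitochondrially encoded transcripts it was 12 and 0.14 (camera, adjusted p = 0.0042, and adjusted p = 0.80 with an estimated correlation). In the last 4 lists 0 genes passed when adjusted over the list alone. Transgenic library 2, which held the most exocrine pancreas RNA, had the highest score in all 5 lists. It also had the lowest TMM factor, 0.848 against 0.967 to 1.07 in the others, which raises its CPM values. As a share of unscaled counts it was not highest for fatty acid oxidation (0.614%, with 0.63% in wild-type library 3). The same held for mitochondrial transcripts (5.35%, with 6.04% in transgenic library 1). It stayed highest for one-carbon metabolism, amino acid breakdown and nuclear oxidative phosphorylation. Without transgenic library 2 camera's adjusted p was 0.42, 0.72, 0.72, 0.72 and 0.17 for one-carbon metabolism, amino acid breakdown, fatty acid oxidation, nuclear oxidative phosphorylation and mitochondrial transcripts, with the direction turned for fatty acid oxidation and nuclear oxidative phosphorylation. Without single libraries the medians ran, in that order, from 0.02 to 0.33, 0 to 0.27, 0.01 to 0.28, -0.02 to 0.21 and 0.07 to 0.36, each lowest without transgenic library 2. Calls also ended without wild-type library 2 (0.11 for one-carbon metabolism, 0.20 for amino acid breakdown, 0.31 for fatty acid oxidation and 0.089 for mitochondrial transcripts) and without wild-type library 1 (0.052 for one-carbon metabolism, 0.25 for fatty acid oxidation and 0.40 for nuclear oxidative phosphorylation).

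Markers of other tissues differed between libraries. Of 23 exocrine pancreas genes 22 had positive fold changes, with a median log2 fold change of 0.86 (camera, adjusted p = 1.1e-11, and adjusted p = 0.77 with an estimated correlation). The carboxypeptidase genes cpa1, cpa4 and cpa5 had 1.28 ± 0.35, 1.27 ± 0.46 and 1.02 ± 0.37. Without transgenic library 2 the median was 0.34, cpa4 was at 0.74 and cpa5 at 0.62. Scores were -0.80, 0.20 and -0.50 in wild-type and -0.34, 1.18 and 0.26 in transgenic libraries, with an exact two-sided permutation p of 0.20. Of 11 pancreatic islet genes 7 were positive at a median of 0.68 (camera, adjusted p = 0.0042, and adjusted p = 0.77 with an estimated correlation), and 4 passed when adjusted over the list alone, the smallest at an adjusted p of 0.037 by edgeR, while 0 passed over all genes. The insulin gene ins had 13, 80 and 3 counts in wild-type and 27, 500 and 341 in transgenic libraries, and the log2 fold changes were 3.25 ± 1.01 for ins, 2.67 ± 0.86 for the glucagon gene gcgb and 2.23 ± 0.72 for the somatostatin gene sst1.1. Without transgenic library 2 they were 2.53, 1.47 and 1.47, and without wild-type library 2 they were 4.95 for ins and 3.28 for gcgb. The median of the islet list was 0.37 without wild-type library 1, 1.53 without wild-type library 2 and 0.45 without wild-type library 3, and its call ended without wild-type library 1 (0.23), transgenic library 2 (0.054) or transgenic library 3 (0.051). Of 19 eye and nervous system genes 18 had negative values, with a median of -0.36 (camera, adjusted p = 0.0049, and adjusted p = 0.73 with an estimated correlation), among them syt1a at -0.86 ± 0.35, stmn1b at -1.20 ± 0.54 and snap25b at -0.80 ± 0.41. The values of these 3 genes rested on wild-type library 3 and were -0.27, -0.31 and -0.25 without it, although that library had the lowest wild-type score for the list, 0.02 against 0.27 and 0.17. That call ended without wild-type library 1 (0.099, median -0.15) or transgenic library 2 (0.33), and 0 of its genes and 0 of the exocrine genes passed when adjusted over the list alone.

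Intestine markers had a median log2 fold change of -0.43, with 16 of 19 negative (camera, adjusted p = 0.092), and wild-type library 2 stood apart with a score of 1.68 against -0.84 to 0.19 in the other 5 libraries. The same library scored highest for skeletal muscle (1.02), stellate cells and fibroblasts (1.0), skin epidermis (0.93), kidney (0.68) and bile duct (0.35). Its intestine markers took 0.256% of the counts, against 0.0844 to 0.125% in the others. Of these 5 lists, camera's adjusted p was 0.90 for skeletal muscle (5 of 26 positive), 0.70 for stellate cells and fibroblasts (1 of 16), 0.70 for skin (7 of 17), 0.63 for kidney (6 of 13) and 0.91 for bile duct (4 of 12). In the skin, kidney and leukocyte lists camera's direction was up while the median was negative, and in glycolysis it was up while the mean was negative. Macrophage and leukocyte markers had 10 of 21 positive (0.19), endothelial markers 14 of 19 (0.31) and erythrocyte markers 9 of 13 (0.31).

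**Figure D2:**
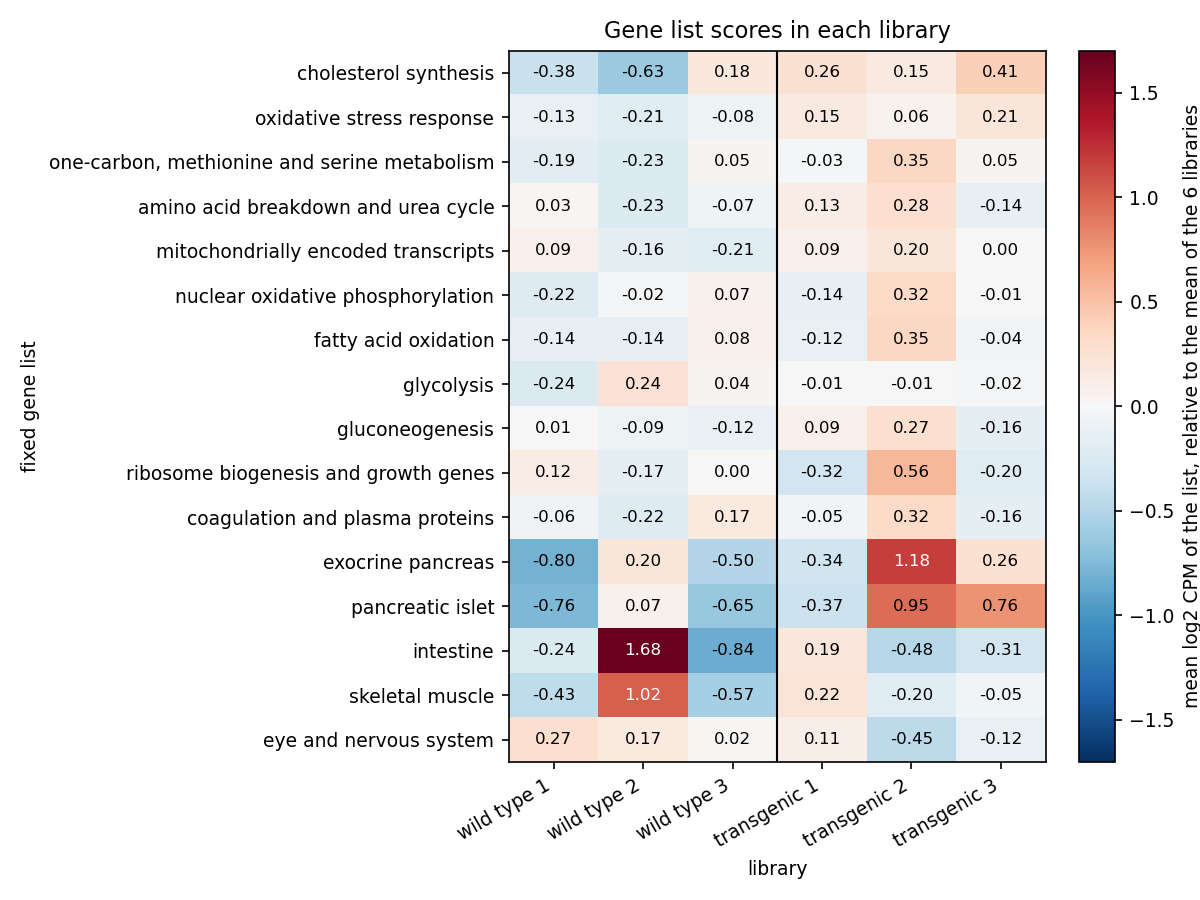
Mean log2 CPM of 16 gene lists in each of the 6 liver libraries (columns, 3 wild-type then 3 transgenic), relative to the mean of the 6 libraries, with red above and blue below it. Cholesterol synthesis runs from -0.63 to 0.18 in wild-type and from 0.15 to 0.41 in transgenic libraries, intestine markers reach 1.68 in wild-type library 2 and exocrine pancreas markers 1.18 in transgenic library 2.

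The remaining lists were not called by camera. Fatty acid and triglyceride synthesis had 13 of 22 genes positive at a median log2 fold change of 0.18 (adjusted p = 0.18), with 0.88 ± 0.41 for the desaturase gene fads2 and 0.83 ± 0.40 for the elongase gene elovl2. Both values rested on transgenic library 3 and were 0.31 and 0.29 without it. Coagulation and plasma proteins, secreted by hepatocytes, had 27 of 33 positive at 0.11 (0.18), while cp, the ceruloplasmin gene, had -0.85 ± 0.27, or -0.56 without wild-type library 1. Complement and acute phase genes had 19 of 32 negative at -0.03 (0.18). Lipoproteins had 7 of 11 positive at 0.03 (0.90), with 0.69 ± 0.29 for apoeb, or 0.43 without transgenic library 1. Bile acid synthesis and transport had 6 of 11 negative at -0.05 (0.90), with -0.92 ± 0.54 for cyp7a1a, which ran from -1.83 without transgenic library 2 to -0.42 without wild-type library 2. Adjusted p-values and medians were 0.19 and 0.10 for xenobiotic metabolism (19 of 27 positive), 0.19 and 0.10 for the cell cycle (21 of 32), 0.47 and -0.07 for the unfolded protein and amino acid stress response (11 of 23), 0.47 and -0.13 for heat shock (6 of 15), 0.39 and 0.16 for vitellogenins and estrogen response (9 of 11), 0.91 and 0.01 for insulin and FOXO signalling (12 of 23, mean -0.02) and 0.80 and 0.06 for liver transcription factors (11 of 17). The circadian clock list had 15 of 30 positive at -0.01 (0.88, direction up), and npas2 passed when adjusted over the list alone (edgeR, adjusted p = 0.022). Over all 37 lists camera called 9 higher and 1 lower with the preset correlation and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. The 10 calls became 6 without wild-type library 1, 18 without wild-type library 3 and 16 without transgenic library 1. Without transgenic library 2 there were again 10, but 3 of the original 10 were among them, and without wild-type library 2 there were 14, with 6 of the original 10. fry, which tests whether the genes of a list move on balance in a single direction without comparing them with other genes, called 0, with a smallest unadjusted p of 0.011.

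The authors' deposited table also lists, for 971 genes, the exon that differed most between the groups after correction for the gene's counts. There, 27 genes were past an adjusted p of 0.05 in the authors' table, with 12 exons higher and 15 lower in transgenic livers. The smallest adjusted p was that of an exon of zgc:161979 on chromosome 16 (48971064 to 48971192, Zv9), at a log2 ratio of -1.09 and an adjusted p of 8.2e-33. An exon of CR388129.1 on chromosome 15 (38777692 to 38777952) had a log2 ratio of -1.35 in the authors' table, with an adjusted p of 3e-19. The authors' test is a chi-square on exon counts of the groups, per the file headers, so it holds no spread between libraries. For foxn3 the authors' table gives no such exon.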

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

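The tests with edgeR's newer method and without wild-type library 2 and transgenic library 2 were chosen after the results were seen; the others were fixed before. In simulated data at these depths edgeR recovered 20% of genes changed 2-fold and 90% of those changed 4-fold, all taken from genes above 2 CPM. Those data held many changed genes, which makes the adjusted threshold easier to pass, and errors independent between genes. In the real data edgeR did not call foxn3 at a 6.69-fold difference (adjusted p 0.11). The simulated shares may therefore overstate the recovery in the real data. The count of genes higher was 1 with DESeq2, with the replicate block, and on log2(FPKM + 1) and log2(FPKM + 0.1), and 0 to 1 when single libraries were left out (1 without wild-type library 3). The count lower was 0 in every alternative run. The fold change of foxn3 kept its direction throughout. It passed the threshold with DESeq2 (2.73), the replicate block (2.81), log2(FPKM + 1) (2.64) and log2(FPKM + 0.1) (2.74), and lay between 2.5 and 3.11 without single libraries. Genes at an unadjusted p under 0.05 numbered 238 to 801 without single libraries, 846 without both doubted libraries, and 637 with the replicate block. Called lists numbered 0 with an estimated correlation, 0 with fry, 6 to 18 without single libraries (of which 3 to 10 were among the original 10, fewest without transgenic library 2), and 16 without both doubted libraries, of which 4 were among the original 10. Without those libraries the direction turned for fatty acid oxidation (adjusted p 0.52), amino acid breakdown (0.76) and nuclear oxidative phosphorylation (0.76). Without single libraries, adjusted p ran from 0.00019 to 0.72 for fatty acid oxidation and from 4.7e-06 to 0.72 for nuclear oxidative phosphorylation. Single-library ranges of log2 fold changes that crossed 0 were -0.62 to 0.11 for igfbp1a, -0.27 to 0.37 for g6pca, -0.32 to 0.37 for pck1, -0.21 to 0.11 for slc2a2, -0.05 to 0.31 for PKLR and -0.09 to 0.27 for fbp1b. On log2(FPKM + 1) pck1 was 0 and g6pca -0.02, and on log2(FPKM + 0.1) 0 and -0.03. The cause of these shifts was not tested. Of the other values, 1004 kept their direction and side and 39 list calls ended. Deviations of same-numbered libraries correlated at 0.34, -0.11 and 0.16, and 3 of the 6 libraries correlated best with their own number, so the numbers were not taken to pair the samples. The replicate block called 10 lists, 9 of them among the original 10 (fatty acid oxidation was at 0.052), and among named genes it changed only the call of foxn3.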

Other observations

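The tests below on pancreas carryover, the transgene, the hepatocyte share, the clock phase and the handling response were chosen only after the results were seen, while the test without wild-type library 2 and the splits of the samples were fixed before. The criteria of the clock phase and hepatocyte share tests, and the lists used in the latter, were also changed after their results were seen. The genes cish, socs3b and pim1, each a known target of STAT proteins, had log2 fold changes of -0.99 ± 0.26, -0.75 ± 0.25 and -0.74 ± 0.18 (SE, n = 3 libraries per group), with groups that did not overlap. Wild-type library 2 held the highest level of each, at 116, 51.8 and 126 CPM, and without it cish was at -0.65 and socs3b at -0.42. They were set side by side after their values were seen, and no list of STAT targets was tested. trib3, a stress-induced gene, had -0.83 ± 0.30, or -0.43 without wild-type library 2, and aurkb, a mitotic kinase gene, 0.71 ± 0.25.

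From the 30 genes of the circadian clock list, 14 were picked as activator or repressor genes after their values were seen, leaving out 16 that include clock3 and 6 cryptochrome genes. The whole list had 15 values above 0 and 15 below, and the 16 genes left out had 9 above 0, with 1 at an edgeR unadjusted p under 0.05, and 7 below, with 0. Of those picked, all 5 activator genes had values above 0, with 3 at an edgeR unadjusted p under 0.05, and 8 of 9 repressor genes had values below 0, with 1 at such a p. The activator genes npas2, clock and arntl1b had log2 fold changes of 0.94 ± 0.19, 0.76 ± 0.29 (0.45 without transgenic library 3) and 0.69 ± 0.29, and the repressor genes ran from -2.47 ± 0.78 for nr1d4b, or -1.36 without wild-type library 1, to 0.53 ± 0.47 for per2, with per3 at -0.03 ± 0.28. An index of the 5 activator genes minus the 9 repressor genes was -1.17, -0.96 and 0.38 in wild-type and 0.60, -0.50 and 1.65 in transgenic libraries, with an exact two-sided permutation p of 0.20. With clock3 and the cryptochrome genes added, 6 minus 15 genes, that p was 0.30. nr1d4b was at 38.8 and 14.8 CPM in wild-type libraries 1 and 2 and between 2.01 and 4.98 in the other 4 libraries.

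mycb and egr1 stood lower in the transgenic libraries, and a different phase of the clock at collection may account for part of it. Within the groups the deviations of mycb and of the clock index had a Pearson correlation of -0.77 (exact permutation p 0.056 over 36 within-group permutations, adjusted 0.11 over 2 relations) and a Spearman rho of -0.77 (exact p 0.11). Without wild-type library 3 and transgenic library 3, the libraries farthest out, r was -0.28, so the relation may rest on them. There the deviations were still taken from the means of all 3 libraries of a group. With 2 libraries left in each group, that value cannot decide it. With clock3 and the cryptochrome genes in the index r over all libraries was -0.67 (exact permutation p 0.083). For egr1 r was -0.72 (exact permutation p 0.17, adjusted 0.17) and rho -0.77 (exact p 0.11). Its r was -0.83 without the libraries farthest out and -0.70 with the added genes (exact permutation p 0.14). A weaker handling response was the other explanation, and the 14 other immediate early genes had a median log2 fold change of -0.22, with 11 below 0, where 1/4 of the change of egr1 is -0.33 and the standard error of the difference 0.24. Neither explanation can be told apart from an effect of the transgene, because the libraries are too few and collection times are not in the labels.

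Exocrine pancreas markers were higher in the transgenic group by a mean score of 0.74. Pancreas carried over during dissection in amounts that differ between libraries is a candidate source, since the score spanned 1.0 within the wild-type libraries alone, more than the difference between the groups. The trypsin gene try, the most abundant marker, stood at 506, 1130 and 591 CPM in wild-type and 768, 2090 and 1190 in transgenic libraries, and 0 of the 23 genes are on another list. Islet hormone genes were highest in transgenic libraries 2 and 3, which also scored highest for exocrine markers. They did not follow the exocrine markers in every library. Wild-type library 2 had an exocrine score of 0.20, near the 0.26 of transgenic library 3. Its levels of ins, gcgb and sst1.1 were 6.15, 1.54 and 2.23 CPM, the highest among wild-type libraries, against 29.5, 4.67 and 7.35 in transgenic library 3. An effect of the foxn3 transgene on the exocrine score cannot be told apart from such carryover. The exact permutation p of 0.20 comes from 3 libraries against 3, where 0.10 is the smallest possible.

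Cholesterol synthesis genes scored 0.55 higher in transgenic libraries. A smaller hepatocyte share in the wild-type libraries would lower the other hepatocyte genes there alike. The mean score of 13 other lists of liver products and metabolism differed by 0.08 ± 0.07 (SE). Single lists ran from -0.10 for the lowest to 0.25 for one-carbon metabolism. The cholesterol score exceeded the 13 lists by 0.47 ± 0.27 (SE) and plasma proteins alone by 0.47 ± 0.25. The difference of the 13 lists plus 2 standard errors was 0.22, below the 0.55 of cholesterol synthesis. This met the criterion against a smaller hepatocyte share as the whole cause. That criterion leaves out the spread of the cholesterol score between libraries. With that spread counted, each excess was under 2 standard errors, so the test cannot decide whether a smaller hepatocyte share was part or all of the cause. Other tissues in wild-type library 2 may have contributed. Without that library, which held the most intestine, muscle and skin RNA, the median log2 fold change of the list was 0.34. That is above the 0.26 that is 1/2 of the full value. The group difference of the list's mean score had a standard error of 0.29 without that library, so this decides nothing. Other tissues in wild-type library 2 cannot be told apart from an effect of the transgene with 3 libraries per group.

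The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Genes at an unadjusted p under 0.05 numbered 441 in the real split and up to 2049 in another, and 9 of the 10 splits gave as many as the real split. The split with 2049 set wild-type libraries 1 and 2 and transgenic library 1 against the other 3, which points to a structure of the samples other than the groups. Called lists numbered 10 in the real split and up to 19 in another, with 9 of the 10 splits giving as many. Genes called higher or lower by edgeR were 0 in the real split and 0 in the others, and with 0 in the real split a count of 10 of 10 splits as large was fixed in advance and says nothing about chance. The absolute log2 fold change of foxn3 was 2.74 in the real split and at most 1.14 in the others. With foxn3 groups that do not overlap, a smaller value in every other split was also fixed in advance.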
